A study of Homo sapiens with 8 samples.

How the data were processed

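RNA abundance was measured on 8 Affymetrix oligonucleotide arrays of SH-SY5Y cells, an established human neuroblastoma line of sympathetic neuroblast character. The cells had been stably transfected either with an RNAi construct against DJ-1, the product of PARK7, or with a scrambled control construct. The arrays covered 4 clones, 2 per condition, and each clone was measured on 2 arrays, numbered as replicates 1 and 2 in the sample titles. Clones B and G carried the knockdown construct, and clones H and M the control construct. Per the labels, total RNA was extracted with a phenol reagent, column-purified, checked on a bioanalyser, and labelled with biotin by the manufacturer's one-cycle protocol.

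Per the submitters' processing notes, GCOS and RMA were used, with versions not given in the sources used here. The deposited values were log2 probe-set signals, a scale read from the values themselves. RMA subtracts background, forces the probe intensities of all arrays to one distribution, and combines the probes of a set by median polish. That step can compress large differences and would remove a shift shared by most genes. No detection calls were used here, so a low signal could not be separated from background. The number of arrays, 8, limits the precision of every value. The table had 22277 probe sets, of which 62 were manufacturer controls left out of the tests, leaving 22215. The array annotation gave 19064 of these 1 gene, 1043 several genes and 2108 no gene. Of those with 1 gene, 19052 were matched by gene ID to current RefSeq symbols, and 11963 distinct genes had at least 1 probe set. Probe sets with several genes were not named. RefSeq was used for names and for gene order only, so no coordinates are given. Listed genes without a probe set of their own are not analysed here.

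Differences between knockdown and control were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with clone as a random block through duplicateCorrelation (statmod 1.5.0). Tests were two-sided, with Benjamini-Hochberg adjustment over the 22215 probe sets and a threshold of 0.05. Pairs of clones were compared in a limma fit with 1 mean per clone and the duplicate spread pooled over all 8 arrays. The consensus correlation within clones was -0.068, so the block narrowed the errors slightly against a fit of independent arrays. That fit without a clone block called 489 probe sets, against 657 with it. With the replicate number in the model, the consensus correlation was 0.235. The labels do not say whether the duplicates of a clone were separate cultures, and p-values therefore measure the spread among these arrays, which may be technical. A fit to clone means, 2 clones against 2, was the alternative that treats the clone as the unit.

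Gene lists, 31 in all with 636 measured genes of 726 listed, were fixed before the data were examined, as were the tests, their alternatives and the rule for naming genes. Lists were tested with cameraPR at a preset correlation between genes of 0.01, again with the correlation estimated for each list, and with fry, with 1 probe set per gene, the one with the highest mean. The marker lists covered mesenchymal neuroblastoma cells, fibroblasts and smooth muscle, Schwann and melanocytic cells, leukocytes and epithelium. The named genes were PARK7 and RET with every probe set. To these were added the 12 largest rises and 12 largest falls among called probe sets with 1 gene, with no overlap between the arrays of the conditions, and with a brighter condition at or above the median of all probe-set means (8.06). Up to 4 members of each list with the smallest p were added, and the 5 largest differences in each direction between clones of one condition. Counts of named probe sets include only part of the list members that were not called, picked for mention in the text. Where a gene had several qualifying probe sets, the brightest was used. Values within replicate numbers, list tests between replicate numbers, the list test without PARK7 and the scan of neighbouring genes were added after the data were seen. Genes named by replicate number or by their place among neighbouring genes were chosen after their values were seen.

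Replicate numbers were checked for pairing before calls were compared. The deviations of same-numbered arrays from their clone means correlated, across probe sets, in each of the 6 pairs of clones, from r = 0.42 for H and M to r = 0.78 for B and G. The pairing is thus a hint from the data on numbers that the titles give. A fit with the replicate number as a block is printed where it changed a call or moved a count by over 1.5 times. Within-replicate differences are given for PARK7, RET, the count of changed probe sets, and the cell cycle and chaperone lists.

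The fits were tested on simulated data with the levels, duplicate noise and replicate shift of the real arrays. For knockdown against control over 22215 probe sets, 100 probe sets were changed by 1 and 100 by 2 on the log2 scale. When each probe set had its own clone variance, the fit with clone as a random block recovered 92 of the first and 98 of the second, and 33.8% of its 287 calls were false. The fit to clone means recovered 75 and 93, with 3.45% false. A further simulation, added after this result was seen and with the clone variance set by hand in fixed proportion to noise, gave 7.25% false calls with the random block. A single correlation for all probe sets thus understated the error of probe sets that vary strongly between clones in the first simulation. For clone H against M, the simulated recovery was 71 and 95, with 0 false calls without the replicate block, and 99 and 100, with 5.69% of 211 calls false, with it. Each of these simulations was a single draw. For the lists, no clone variance was added and noise was drawn for each probe set on its own. Correlation between genes beyond the replicate shift was thus left out. For the real cell cycle list it was estimated at 0.54 with the replicate number in the model. In each of 20 draws 1 list was shifted by 0.5, and it was called in all 20. Of the 30 unshifted lists, some of which share members with it, 0.9 were called per draw on average (range 0 to 2), with at least 1 called in 13 of the 20 draws. The alternatives tried were other clone structures, the replicate block, median centring, quantile normalization, removal of dim or less specific probe sets, other variance priors, array weights, a threshold of 0.01, and omission of each array or clone.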

Results

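The data were log2 signals of 22215 probe sets on 8 arrays of SH-SY5Y neuroblastoma cells. DJ-1, a redox-responsive protein encoded by PARK7 and mutated in recessive Parkinson disease, had been silenced in clones B and G. Clones H and M carried a scrambled construct, and each clone was measured in duplicate, giving 4 arrays per condition. The median signal per array lay between 8.03 and 8.08. The 3' to 5' difference of ACTB, a measure of RNA integrity, ranged from 0.24 to 0.46 in the knockdown arrays and from 0.10 to 0.30 in the control arrays.

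The first comparison asked whether the targeted transcript and RET, the signalling receptor of the GDNF family of neurotrophic factors, differed between knockdown and control clones. PARK7 fell by 2.90 on the log2 scale (SE 0.09), from 13.08 ± 0.09 in control arrays to 10.18 ± 0.18 in knockdown arrays (SD, n = 4 arrays each), a 7.46-fold difference. The limma adjusted p was 1.67e-06, and all 4 knockdown arrays lay below all 4 control arrays. RET fell by 1.85 (SE 0.16) on its brightest probe set, from 12.50 ± 0.28 to 10.65 ± 0.29 (SD, n = 4 each), a 3.61-fold difference with limma adjusted p = 0.0012. The other 2 RET probe sets differed by -1.68 and -1.77, 3.20-fold and 3.42-fold, with limma adjusted p = 0.0042 and 0.0059. In clone means, PARK7 stood at 10.29 in B and 10.07 in G against 13.13 in H and 13.03 in M. RET stood at 10.56 and 10.74 against 12.32 and 12.67.

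When duplicates were averaged and the clone was the unit, PARK7 kept limma adjusted p = 0.0097 and RET had adjusted p = 0.066. Within replicate 1, PARK7 differed by -2.84 and RET by -1.46 (limma adjusted p = 0.016 and 0.044), and within replicate 2 by -2.96 and -2.24 (adjusted p = 0.023 and 0.16).

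**Figure D1:**
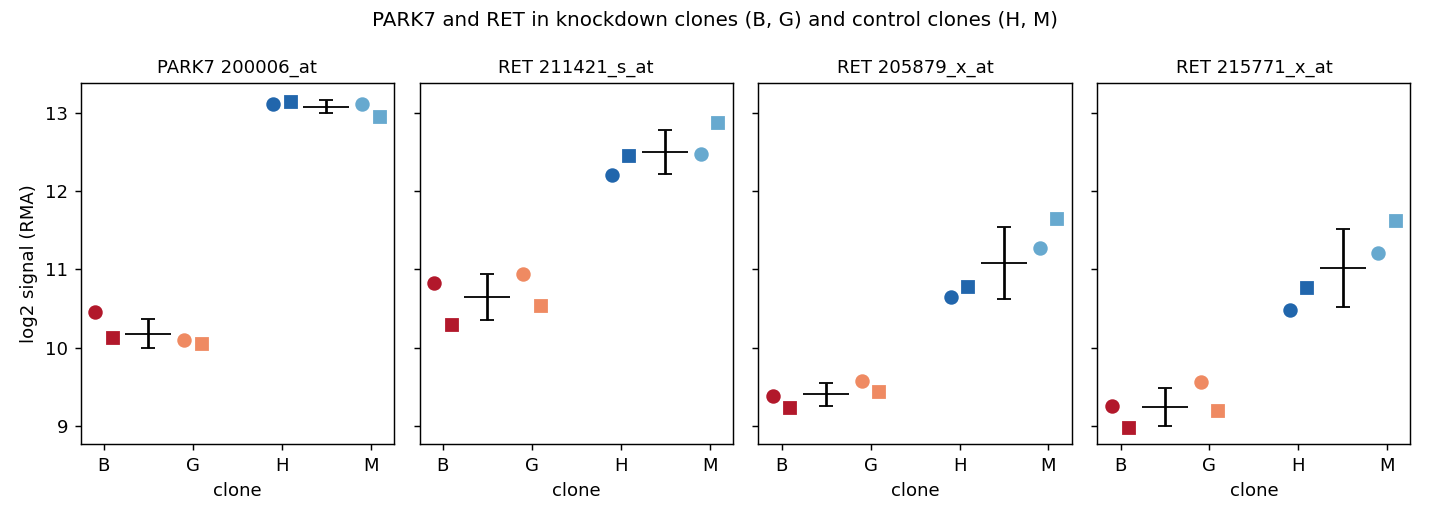
Log2 signal of the PARK7 probe set and the 3 RET probe sets (vertical axis) in knockdown clones B and G and control clones H and M (horizontal axis), with circles for replicate 1, squares for replicate 2, and bars for the condition mean ± SD over 4 arrays. PARK7 averaged 10.18 in the knockdown arrays and 13.08 in the control arrays, and the brightest RET probe set averaged 10.65 and 12.50.

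The wider comparison asked which other transcripts differed between the conditions. Among the named genes with the largest rises were NELL1 (+2.09), a secreted differentiation factor, and GRM8 (+2.01), a metabotropic glutamate receptor. STMN4 (+1.94), a neuronal microtubule regulator, PTBP2 (+1.57), a neuronal splicing repressor, and ANO3 (+2.09), of the anoctamin family, rose with them. The axon guidance receptor gene PLXNC1 (+1.42), the adhesion gene FLRT3 (+1.41) and the lipid transporter gene ABCA12 (+1.43) completed this group. PTBP2 rose from 9.79 ± 0.19 to 11.36 ± 0.13 (SD, n = 4 each), with limma adjusted p = 4.06e-04. FLRT3 lost its call with the replicate block (limma adjusted p = 0.083). Of the other GRM8 probe sets, one rose by 2.67 (limma adjusted p = 0.0014) and the brightest differed by 0.51 (adjusted p = 0.071).

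For 4 of the 12 largest rises, another probe set of the same gene at or above the median level differed by under 0.25, a limit set after the data were seen that leaves out GRM8. One probe set of GNAS, which encodes the stimulatory G protein alpha subunit, rose by 3.09 (SE 0.34), while the brightest GNAS probe set differed by 0.08. Another GNAS probe set differed by 1.78 (limma adjusted p = 0.066). The brightest averaged 14.59, near the highest signal on each array (14.88 to 14.99), which leaves little room for a rise. GNAS probe sets further below that level, at 13.27 and 6.98, differed by 0.14 and 0.09. A limit on the signal was thus not shown to explain the disagreement. For CDC42, one probe set rose by 2.17 and another by 1.58 (limma adjusted p = 0.0017 and 4.06e-04). The brightest CDC42 probe set differed by 0.17 and the next brightest by 0.05. JMJD6, a nuclear hydroxylase gene, rose from 7.38 ± 0.36 to 8.88 ± 0.36 (SD, n = 4 each) on one probe set and differed by -0.02 on the brightest. RUFY3, a gene of neuronal polarity, rose by 1.52 on one probe set, with differences from -0.16 to 0.85 on the others. By this limit, probe sets disagreed for 7 of the 45 genes that had a called 2-fold probe set and several probe sets.

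Among the falls, DKK2, a secreted modulator of Wnt signalling, had the lowest difference, -3.94 (SE 0.76), followed by TFPI2, an extracellular protease inhibitor gene, at -2.98 (SE 0.55). Also lower were the complement gene C7 (-2.44), the mesenchymal cadherin gene CDH11 (-2.12), POPDC2 (-2.05) and TNS3 (-1.92), which encodes a focal adhesion protein. NPY, a neuropeptide of sympathetic neurons, fell by 1.91, from 12.50 ± 0.42 to 10.59 ± 0.74 (SD, n = 4 each). The growth factor signalling adaptor gene GAREM1 (-1.83) and the neurite outgrowth genes NAV2 (-1.68) and DPYSL3 (-1.63) fell as well. PARK7 and RET were themselves among the 12 largest falls.

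In all, 657 of 22215 probe sets changed, 340 higher and 317 lower in the knockdown, and 114 of them by 2-fold or more (61 higher, 53 lower). With duplicates averaged, limma called 1 probe set, that of PARK7, with 3512 at an unadjusted p under 0.05. Leaving out arrays B1, B2, G1 or G2 gave 225, 69, 212 or 207 changed probe sets, and leaving out H1 or H2 gave 1544 or 3751. Without the whole of clone B or G the count was 13 or 22, and without H or M it was 8685 or 2117. Within replicate 1 alone limma called 18 and within replicate 2 alone 1, with 3403 and 2850 at an unadjusted p under 0.05, and the differences of the 2 replicates correlated across probe sets at 0.73. Of 52 further named probe sets called here, 28 kept their call without B1, 14 without B2, 29 without G1, 25 without G2, 36 without M1 and 41 without M2. Without the whole of clone B 3 kept it, without clone G 5, and 0 kept it in limma with clone means. In limma without the clone block 38 kept it. Of 22 named probe sets not called here, list members picked for mention, 22 passed without H2, 10 without H1, 1 without M2, 22 without clone H and 12 without clone M. In a single simulated draw in which each probe set had its own clone variance, 33.8% of the calls of the limma fit used here were false. With the clone variance in fixed proportion to noise it was 7.25%. Both depend on how many probe sets were changed in the simulation, so neither measures the false share of the 657.

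**Figure D2:**
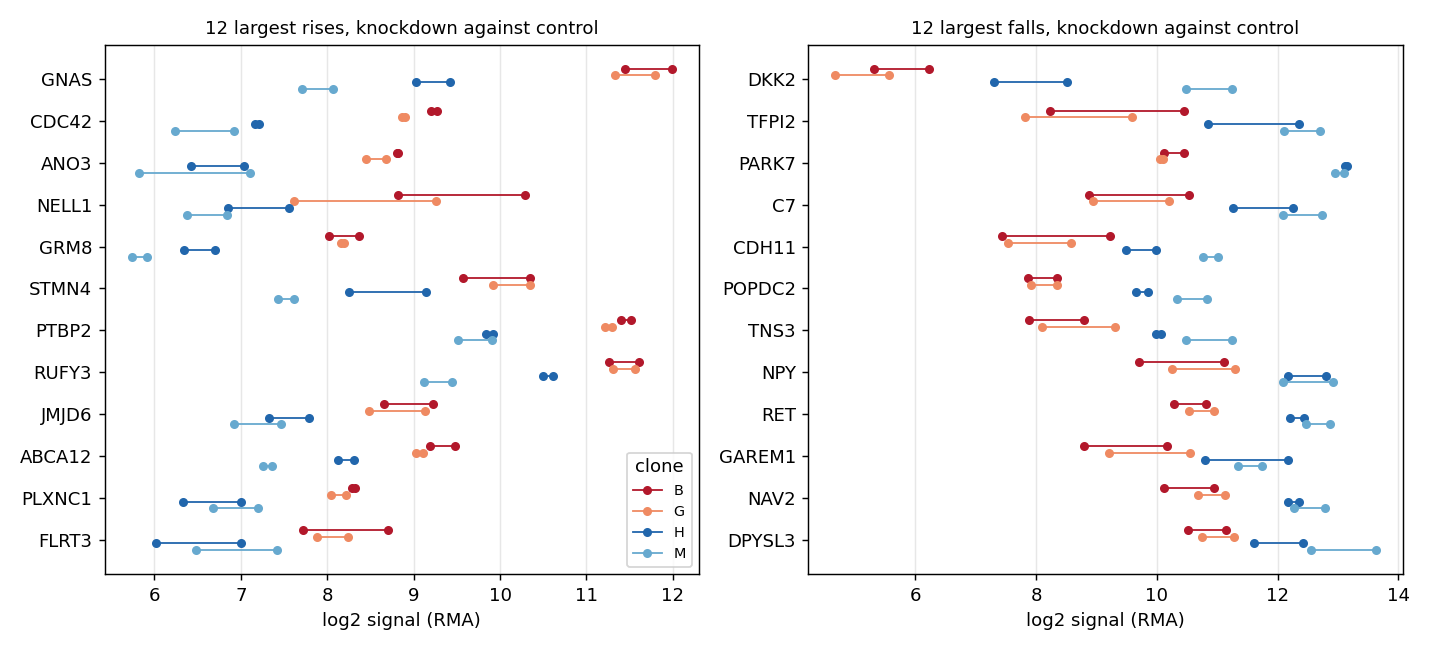
Log2 signal (horizontal axis) of the 12 largest rises and the 12 largest falls by the naming rule (vertical axis), with points for the 2 arrays of each clone joined by a line. For PTBP2 the knockdown arrays averaged 11.36 and the control arrays 9.79, while for DKK2 control clone H stood at 7.91 and control clone M at 10.86.

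Of 43 measured genes of matrix and adhesion, 37 had a negative difference and 3 fell: ITGB1 (-1.16, SE 0.10), the beta 1 integrin gene, LAMC1 (-0.94), a laminin chain gene, and CDH11 (-2.12). The list median was -0.27 (cameraPR adjusted p = 4.80e-06). The call was lost with adjusted p = 0.41 with an estimated correlation, and adjusted over the list alone 4 members fell. COL4A1 differed by -1.21 with adjusted p = 0.077, and fell in the replicate block fit (limma adjusted p = 0.046). The same list was lower in control clone H than in control clone M, with a median of -0.38.

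The mesenchymal neuroblastoma markers had a median of -0.17 over 22 members (cameraPR adjusted p = 0.0028, and adjusted p = 0.41 with an estimated correlation). CDH11 alone fell, with 5 members lower adjusted over the list alone. NOTCH2 differed by -1.83 and did not pass without the replicate block but fell with it (limma adjusted p = 0.052 and 0.030), while S100A6 differed by -0.63 and ANXA2 by -1.08. The list was lower in H than in M by a median of -0.38, and without clone M its median was -0.08 with adjusted p = 0.14. The fibroblast and smooth muscle markers had a median of -0.27 over 18 members (cameraPR adjusted p = 0.035, and adjusted p = 0.70 with an estimated correlation). By limma 0 of these 18 passed, 0 adjusted over the list alone, and 4 had an unadjusted p under 0.05. Of the 18, 15 had a negative and 3 a positive difference. PDGFRA differed by -1.65, COL3A1 by -1.89 and ACTA2 by -0.97, while COL5A2 differed by 0.32. The median of these 18 markers was -0.56 in H against M. Without clone M their knockdown median was -0.06, with adjusted p = 0.63. Leaving out array B2, M1 or M2 also ended this call (adjusted p = 0.063, 0.21 and 0.089), as did leaving out clone B (0.054) or G (0.064), quantile normalization (0.077) and the replicate block without the clone block (0.052).

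Of 36 cell cycle genes, 35 had a positive difference, the median was 0.48, and cameraPR gave adjusted p = 1.06e-04, lost with adjusted p = 0.70 with an estimated correlation. MCM4, a subunit of the replicative helicase, was the member that rose (+0.66, SE 0.14), also when adjusted over the list alone. MCM5 (+0.73), MCM2 (+0.60) and MCM7 (+0.44), of the same complex, passed with the replicate block (limma adjusted p = 0.015, 0.0093 and 0.023, against 0.075, 0.12 and 0.13 without it). Between replicate numbers, 31 of the 36 members were lower in replicate 2, with a median of -0.84 (adjusted p = 0.12 with an estimated correlation). Within replicates 1 and 2 the knockdown median was 0.43 and 0.59.

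Genes of the ATF4 and amino acid response had a median of 0.42 over 28 members, 26 of them positive (cameraPR adjusted p = 0.0017, and adjusted p = 0.70 with an estimated correlation). VLDLR, a lipoprotein receptor gene, was the 1 member that rose (+1.02), in all genes and adjusted over the list alone, and it lost its call with the replicate block (limma adjusted p = 0.053). SLC7A11, the cystine transporter gene, differed by 1.88 (SE 0.71) with adjusted p = 0.19. Between replicate numbers, 17 of the 28 members were higher in replicate 2 (adjusted p = 0.12 with an estimated correlation). Between control clones, the median of H minus M was 0.43 (adjusted p = 0.90 with an estimated correlation). Without clone M the knockdown median of the list was 0.21, with adjusted p = 0.086. Endoplasmic reticulum chaperones and quality-control genes had a median of -0.25 over 20 members (cameraPR adjusted p = 0.0072, and adjusted p = 0.70 with an estimated correlation). Within replicates 1 and 2 that median was -0.08 and -0.35. EDEM1 (-0.53), of glycoprotein degradation, and CRELD1 (-0.62) fell, and adjusted over the list alone 4 fell. This call ended without array H2 (adjusted p = 0.12) or clone G (0.084), and 9 of the 20 were higher in replicate 2.

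The Parkinson disease list, 15 measured genes, had a positive median (0.04) and a negative mean (-0.12), with a test direction of lower (cameraPR adjusted p = 0.011, and adjusted p = 0.32 with an estimated correlation). PARK7, the targeted transcript, was the member that fell. Without it the other 14 had a mean of 0.08 and a test direction of higher (cameraPR adjusted p = 0.54), which ended the call. Adjusted over the list alone, 2 fell, PARK7 and DNAJC13, and 1 rose, SYNJ1, and MAPT, the tau gene, differed by 0.64 with adjusted p = 0.14. With PARK7 in the list, the call also ended without arrays H1 or H2 (adjusted p = 0.17 and 0.12) and without clone H (0.86).

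Among the GDNF family ligands and receptors, 10 measured, RET fell, also adjusted over the list alone, and the other 9 did not pass (list median -0.08, cameraPR adjusted p = 0.10). The co-receptor gene NCAM1 differed by 0.51 and the ligand gene NRTN by -0.68. Of 22 transcription regulators of RET and sympathetic neuroblasts, EYA1 (+1.10) and LMO1 (+0.57) rose and KLF7 (-0.46) fell, and adjusted over the list alone 4 rose and 1 fell (list median 0.08, cameraPR adjusted p = 0.30). LMO1 lost its call with the replicate block (limma adjusted p = 0.058). Among 28 receptor tyrosine kinases and neurotrophin receptors, ERBB4 (+1.74) and KIT (+1.12) rose and IGF1R (-0.64) fell, with 3 higher and 2 lower adjusted over the list alone (list median -0.14, adjusted p = 0.23). Feedback genes of MAPK and AKT signalling had 1 rise, JUN (+1.01), and 2 falls, IRS2 (-0.49) and SPRY4 (-0.66), of 21 measured, with 3 and 5 adjusted over the list alone (median -0.19, adjusted p = 0.13).

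For catecholamine handling, 21 genes, SLC18A2 (+1.05), the vesicular monoamine transporter gene, and PNMT (+0.39), the adrenaline-synthesising enzyme gene, rose, and NPY fell, with 2 higher and 3 lower adjusted over the list alone (list median 0.07, mean -0.07, test direction higher, adjusted p = 0.96). PNMT did not pass with the replicate block (limma adjusted p = 0.074), while QDPR (-0.46) passed there (0.044, against 0.072 without it). Of 29 genes of neuronal structure and synapse, STMN4 rose and DPYSL3 fell, also adjusted over the list alone (median 0.26, adjusted p = 0.088). Of 8 midbrain dopaminergic transcription factors, 0 passed by limma, 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05 (median -0.11, adjusted p = 0.26).

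Genes of mitophagy and mitochondrial dynamics moved in both directions. Of 19 measured, MFN1, a mitochondrial fusion GTPase gene, fell from 10.40 ± 0.05 to 9.39 ± 0.07 (SD, n = 4 each), and CALCOCO2, an autophagy receptor gene, fell by 1.01 (SE 0.08). FIS1 (+0.56), of mitochondrial fission, and TFAM (+0.43), a mitochondrial DNA packaging factor gene, rose, with 3 higher and 2 lower adjusted over the list alone (list median 0.08, mean -0.01, test direction lower, adjusted p = 0.63). By limma 0 of 28 complex I subunits passed (2 at an unadjusted p under 0.05, median 0.02, adjusted p = 0.93). For the other respiratory chain and ATP synthase subunits it was 0 of 34 (2 at an unadjusted p under 0.05), with a median of -0.0030, a test direction of higher and adjusted p = 0.99. Of 31 antioxidant enzymes 0 passed by limma, with 9 at an unadjusted p under 0.05 (median -0.04, adjusted p = 0.48), though PRDX3, a mitochondrial peroxiredoxin gene (+0.27), passed with the replicate block (limma adjusted p = 0.035, against 0.087). Of 23 NRF2 targets 0 passed by limma, with 4 at an unadjusted p under 0.05 (median -0.04, mean 0.01, test direction lower, adjusted p = 0.78), and the quinone reductase gene NQO1 stood at -1.09 and adjusted p = 0.18.

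Of 34 hypoxia-inducible factor targets, ADM (+0.68) rose and ERO1A (-0.61) fell, also adjusted over the list alone (median -0.07, mean 0.00, test direction lower, adjusted p = 0.23). VEGFA differed by 0.98 with adjusted p = 0.16, and P4HA2 (-0.45) passed with the replicate block (limma adjusted p = 0.045, against 0.095). EPAS1, which encodes HIF-2 alpha, rose by 1.36 among 14 HIF and VHL pathway components, and HIF1A differed by -0.35 with adjusted p = 0.11 (list median 0.05, adjusted p = 0.60, and 2 higher and 1 lower adjusted over the list alone). CDKN1A (-0.69) and TIGAR (-0.62) fell among 19 p53 targets, with 3 lower adjusted over the list alone (median -0.04, adjusted p = 0.15), and CDKN1A lost its call with the replicate block (limma adjusted p = 0.064). BAG3 (-1.24), a co-chaperone gene, fell among 16 cytosolic heat shock genes, also adjusted over the list alone (median 0.03, mean -0.04, test direction lower, adjusted p = 0.996). ISG15 (+0.63) rose among 28 interferon response genes, also adjusted over the list alone (median -0.11, adjusted p = 0.43).

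By limma 0 genes passed among 27 proteasome subunits (median 0.08, adjusted p = 0.14), 15 cholesterol synthesis genes (median 0.13, adjusted p = 0.30), 10 Schwann and melanocytic markers (median -0.16, adjusted p = 0.11), 14 epithelial markers (median -0.09, adjusted p = 0.34) or 13 leukocyte markers (median -0.05, adjusted p = 0.64). Adjusted over the list alone, the count was 0 for each of these and for the complex I, respiratory chain, antioxidant and NRF2 lists, and at an unadjusted p under 0.05 the counts were 2, 3, 3, 2 and 0 in the order given. Of 11 housekeeping genes 0 passed by limma, 3 at an unadjusted p under 0.05, with 1 higher and 2 lower adjusted over the list alone (median -0.08, adjusted p = 0.23). Of 8 RNA interference machinery genes 0 passed by limma over all probe sets, 3 had an unadjusted p under 0.05 and 3 were higher adjusted over the list alone, with a median of 0.20 and cameraPR adjusted p = 0.076. The fry test, which asks whether the genes of a list move one way on balance, gave adjusted p = 0.023 for this list and was past the threshold for no other.

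**Figure D3:**
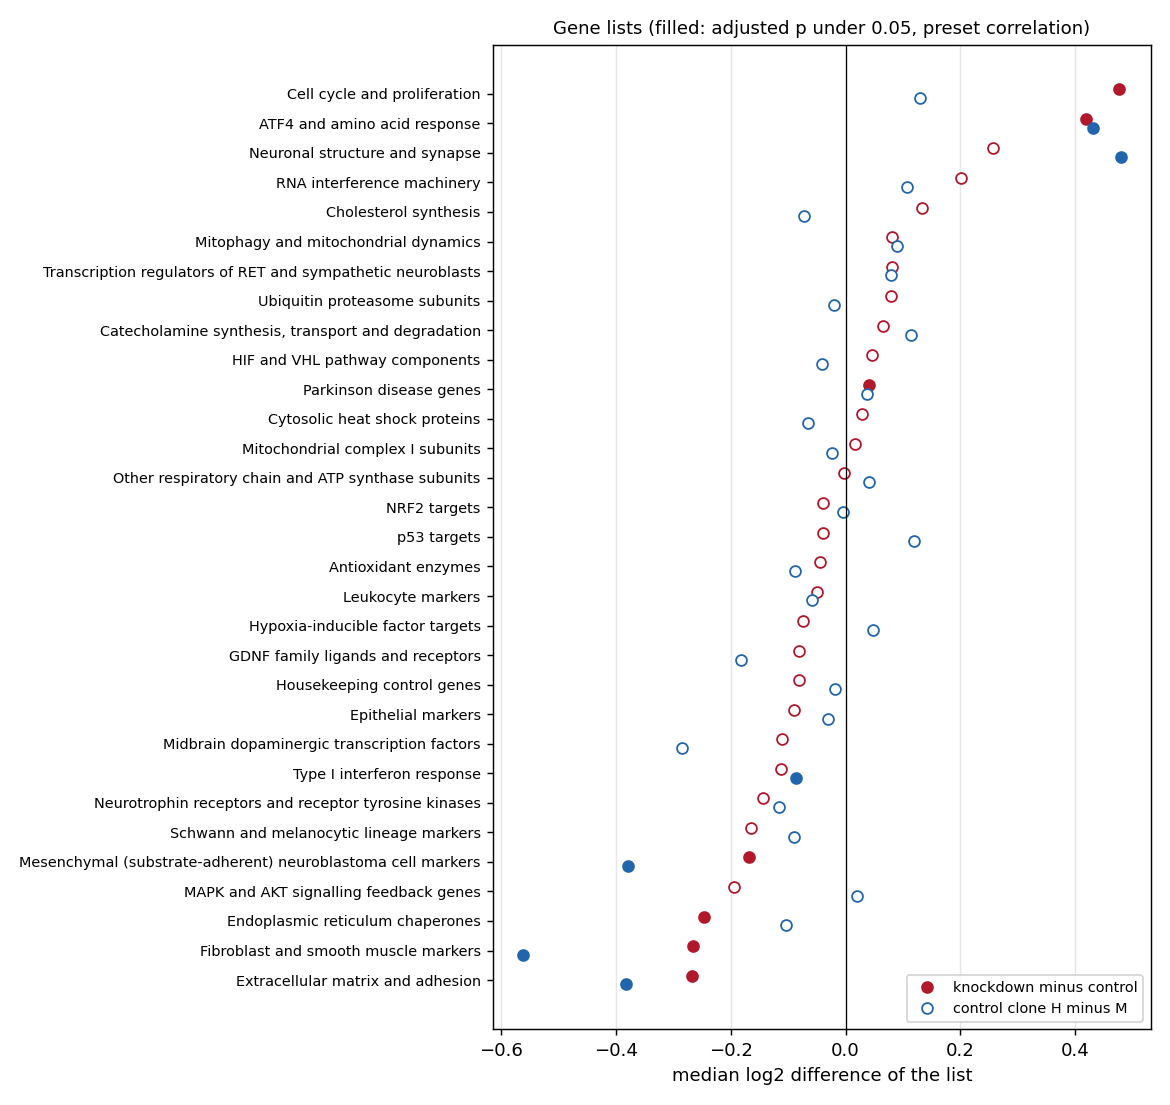
Median log2 difference (horizontal axis) of each of the 31 gene lists (vertical axis) for knockdown minus control in red and control clone H minus control clone M in blue, filled where the cameraPR adjusted p with a preset correlation was under 0.05. The cell cycle list had a knockdown median of 0.48, and the matrix and adhesion list had medians of -0.27 for the knockdown and -0.38 for H against M.

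Clones of one condition were compared to give the background difference between clones. The knockdown clones B and G differed in 1 probe set, that of TIMP1, a metalloproteinase inhibitor gene, which stood at 7.35 in B and 9.31 in G, a difference of -1.96 (SE 0.14, limma adjusted p = 0.024), with 208 probe sets at an unadjusted p under 0.05. With the replicate block there were 2 calls and 651 probe sets at an unadjusted p under 0.05. Both 208 and 651 lay under the share of 0.05 of the 22215 probe sets that chance gives. The tests were thus conservative here, and the few calls do not show how alike B and G were. The TIMP1 call ended without any 1 array of B or G, without M1 or without M2, each giving 0. By cameraPR, complex I subunits (median 0.09) and the other respiratory chain subunits (median 0.07) were higher in B, with adjusted p = 4.31e-04 and 0.0019, and adjusted p = 0.82 with an estimated correlation for both. The matrix and adhesion list (median 0.02) had adjusted p = 0.012, and adjusted p = 0.11 with an estimated correlation.

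The control clones H and M differed more. HSD17B12, a steroid and fatty acid metabolism gene, was at 6.30 in H and 11.26 in M, with 11.34 in B and 11.16 in G. MAB21L2 (-4.54), the gap junction gene GJA1 (-3.97), SEL1L3 (-3.65) and the matrix proteoglycan gene VCAN (-3.52) were lower in H than in M. Higher in H were the neuronal transcription factor gene POU4F2 (+2.84), the serotonin receptor gene HTR1E (+1.41), the lipid transporter gene ABCG1 (+1.36), PTPRN (+1.29) and RUFY3 (+1.27). In total 234 probe sets differed between H and M, 44 higher and 190 lower in H (18.8% higher), and 1538 with the replicate block, 708 higher and 830 lower (46.0% higher). Without G1 or G2 the count was 120, without H1 29, without H2 13 and without M2 62. By cameraPR, the neuronal structure list was higher in H (median 0.48). It kept its call with an estimated correlation (adjusted p = 9.92e-05), as did the 3 lists lower in H, of matrix and adhesion (1.72e-10), mesenchymal markers (2.52e-05), and fibroblast and smooth muscle markers (3.06e-06). The ATF4 and interferon lists lost theirs (adjusted p = 0.90 and 0.26 with an estimated correlation).

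Knockdown and control differences were also set against each other in pairs of clones that shared no array. Across 22215 probe sets, which are not independent replicates, B minus H correlated with G minus M at r = 0.48, and B minus M with G minus H at r = 0.58. B minus G correlated with H minus M at r = -0.099. The variance of the clone difference over the duplicate noise was 1.60 for B and G, 3.05 for B and H, 3.3 for G and H, 3.98 for H and M, 5.84 for B and M and 6.93 for G and M. Of the 657 changed probe sets, 505 had a smaller difference from the knockdown mean in H than in M.

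**Figure D4:**
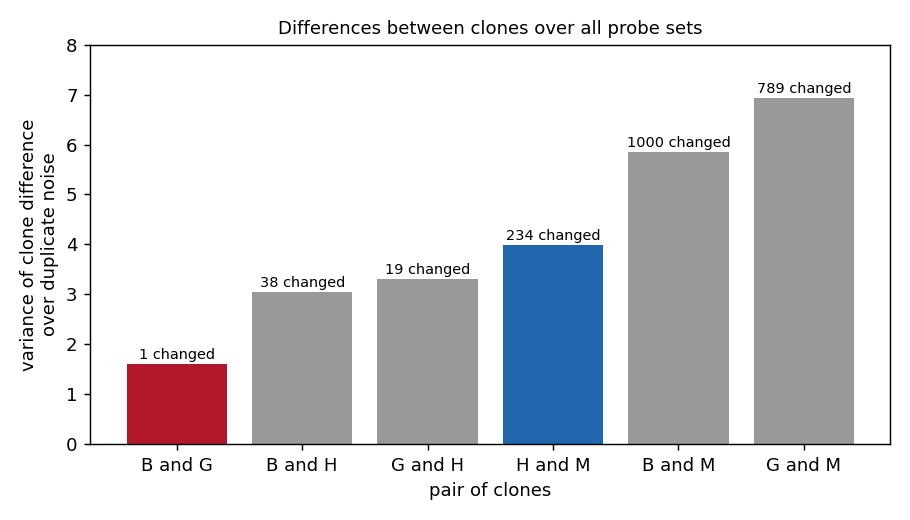
Variance of the difference between 2 clones over the variance of duplicate noise (vertical axis) for the 6 pairs of clones (horizontal axis), over all probe sets, with the number of changed probe sets above each bar. The knockdown pair B and G had the lowest ratio, 1.60, and the control pair H and M had 3.98.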

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

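The correlation of neighbouring genes was set beside the test of copy number only after its result was seen, and the other tests in this part were not chosen that way.

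DKK2, a secreted Wnt modulator, RUFY3 and ABCA12 had knockdown differences whose size depended on the control clone used. The knockdown difference of DKK2 taken against M less that taken against H was -2.96, that of RUFY3 was 1.27 and that of ABCA12 was 0.91, in limma's test of H against M (adjusted p = 0.048, 0.020 and 0.036). For ANXA2 (-1.19) and NQO1 (-1.65), which did not pass for the knockdown, it gave adjusted p = 0.020 and 0.028. MITF, a list member outside the probe sets counted here, had -0.85 with adjusted p = 0.045 in the same test. With the replicate block, 15 more of 76 named probe sets passed this test, among them GNAS (1.33, adjusted p = 3.43e-04), DPYSL3 (-1.07, 0.0029), BAG3 (-0.96, 0.0031), STMN4 (1.18, 0.0070), VLDLR (0.88, 0.0096), GRM8 (0.70, 0.044) and 2 RET probe sets (-0.74 and -0.79, 0.018 and 0.045). Of the 657 changed probe sets, 6 differed between H and M without the block and 61 with it. Among the control arrays, the 3' to 5' difference of GAPDH in H1 stood apart from the others, with 0.846 of the range lying in the gap to the next array. The 3' probe set of the 18S ribosomal RNA control did so too, in H1, with 0.886. These were 2 of 62 groups of 4 arrays tested, and chance gives about 1 in 20. The 5' probe set of the same ribosomal RNA control stood at 9.55 in B1 and at 7.85 in the highest control array.

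The count of 657 changed probe sets was set against regroupings of the arrays. Of 35 splits of the 8 arrays into 4 and 4, 2 gave as many, the real split and the split of replicate 1 against replicate 2 with 2543, so chance could not be excluded by this count, and the other 33 splits gave 0. Replicate number marks a structure of the arrays of its own, and with it as a block the real comparison had 744 calls. Among the 18 splits that hold both replicate numbers equally, the real one gave 657 and the highest other 0, 1 split of 18. With clones kept whole there were 3 splits, of which 1, the real one, gave as many and the highest other gave 0, too few for a share under 0.05. Copy number differences between clones would place changed genes side by side, and 5.46% of 293 changed expressed genes had a changed neighbour in the same direction (exact 95% interval 3.15 to 8.72), 16 genes against a median of 12 in permuted gene orders, with permutation p = 0.27. That interval lay below the share set in advance for copy number as the main cause. It cannot decide, since only 293 of 6802 ordered genes were called and smaller shifts of their neighbours would be missed. The knockdown differences of neighbouring genes correlated at r = 0.034 (permutation p = 0.0040), so copy number stays open. Which of the differences come from DJ-1 and which from the particular clones stays open too, since each condition held 2 clones.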

How the results depend on the processing

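The replicate block without the clone block, the comparison of replicate numbers and the lists without PARK7 were chosen after seeing the data. PARK7 stayed past the threshold in every alternative. RET, on its brightest probe set, did so except with clone means (-1.85, adjusted p = 0.066), and had no probe set left without the suffixes _x_at and _s_at. Within replicate 2 alone RET did not pass either (limma adjusted p = 0.16). The 657 changed probe sets became 1 with clone means, 366 without those suffixes, 1557 with array weights, 99 at an adjusted p under 0.01 and 1568 with the replicate block without the clone block, with a range of 13 to 8685 when an array or clone was left out. The cause of these moves was not tested. Simulated arrays gave calls with clone means too, but their changes were of 1 and 2 on the log2 scale. Of the 657, 114 changed by 2-fold or more, so the simulation does not show whether clone means would find the smaller changes. The replicate block beside the clone block gave 744, 523 of them shared, and among named genes 5 probe sets lost and 8 gained a call. It changed no other call of a named gene or list in this comparison. The 7 called gene lists became 0 with an estimated correlation, and 5 to 10 when arrays or clones were left out. The B and G count of 1 became 0 with only the 4 arrays of both clones or at 0.01, 2 with the replicate block, and 0 to 1 when an array was left out. The H and M count of 234 became 80 with only their 4 arrays, 1538 with the replicate block, 48 without the lowest 40% of probe sets, 108 without the suffixes and 41 at 0.01, with 13 to 206 when an array was left out. The correlation of B minus M with G minus H moved from 0.58 to 0.59 with quantile normalization and 0.65 without the lowest 40%, and that of B minus H with G minus M from 0.48 to 0.47 and 0.58. Median centring cannot move a correlation, so that alternative says nothing of its stability. The Parkinson list turned from lower to higher without PARK7 (median 0.044, adjusted p = 0.54), as that gene carried its call, and no other called gene or list reversed. An arm left with 1 clone was assumed to vary like the other. Without detection calls, dim probe sets such as those of DKK2 in the knockdown (5.44) and of SLC18A2 (6.61 in the knockdown, 5.56 in control) had no measured background.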

Other observations

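The tests on the likeness of clones B and G, on replicate number and on windows of neighbouring genes were chosen after the results were seen, except that of the ratio of spreads, which was chosen before.

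The replicate numbers were compared with clone as a term. TXNIP, a glucose-responsive inhibitor of thioredoxin, differed by -3.01 between replicate 2 and replicate 1 (SE 0.17, limma adjusted p = 5.31e-04). VIP, a neuropeptide gene (-2.11), SNAI2, a transcription factor gene of mesenchymal character (-1.94), and SGK1, a hormone- and stress-responsive kinase gene (-1.87), were also lower. NIBAN1 (+2.36), SLC7A11 (+2.01), FLRT1 (+1.88), CEBPB (+1.76), H2AC6 (+1.72), TACC2 (+1.59) and STC2 (+1.56) were higher. Smaller rises were those of NEBL, CHAC1 (+1.33), H2BC21 (+1.28) and TRIB3 (+1.25). In all 2966 probe sets differed, 1021 higher and 1945 lower in replicate 2. Antioxidant enzymes (median -0.21) kept their list call with an estimated correlation (adjusted p = 8.35e-06), as did housekeeping genes (median -0.13, adjusted p = 0.018). For antioxidant enzymes that value was below the cameraPR adjusted p with the preset correlation (2.83e-05), so the estimated correlation was no stricter a check. The other 8 lists called between replicate numbers lost theirs with an estimated correlation: adjusted p was 0.12 each for the cell cycle, ATF4, proteasome, cholesterol, complex I and NRF2 lists, 0.18 for endoplasmic reticulum chaperones and 0.44 for the other respiratory chain subunits.

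A laboratory batch without regard to gene function was set against a difference in growth or nutrient state. Of the cell cycle genes, 31 were lower in replicate 2, against at most 16 in 10000 random lists matched on mean level. Random lists do not keep the correlation between genes, with which the difference of the list had adjusted p = 0.12, so such a batch stays open. A growth or nutrient state that differed between the replicate cultures stays open beside it: TXNIP and the cell cycle median were lower and the ATF4 median higher in 4 of 4 clones, but these were picked after the pattern was seen on the same arrays, and the ATF4 list too had adjusted p = 0.12 with an estimated correlation. As the labels name no such difference, no biological explanation from the design was tested.

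By the variance of their difference over duplicate noise, clones B and G (1.60) were more alike than any other pair (lowest other 3.05). One culture measured under 2 clone names is argued against by 5 probe sets that differed by 2-fold or more in one direction in both replicate numbers, with 0 doing so in opposite directions. For the knockdown itself making clones alike, 9885 probe sets whose conditions differed by under 0.1 were used. The spread of B minus G there was 0.653 of that of H minus M, below the 0.8 set in advance. The bootstrap 95% interval, 0.635 to 0.673, resampled probe sets, which are not independent replicates. With a single pair of clones per condition, it does not measure how such a ratio varies between pairs, so this explanation stays open. A shared clonal origin or shared handling of B and G could not be tested on those probe sets. The variance ratio there was 1.43 for B and G and 0.882 for the lowest other pair, which by the rule first written would have counted against this explanation. That rule was set aside only after this result was seen, because the limit on the condition difference by itself lowered the ratio of the 4 pairs across conditions 3.09 to 6.39 times, against 1.12 and 1.90 times for the pairs within a condition, so a shared origin or handling stays open.

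Neighbouring expressed genes, 6802 in RefSeq order, had correlated differences at r = 0.069 for B minus G, r = 0.045 for H minus M and r = 0.034 for knockdown minus control (permutation p = 1e-04, the smallest that 10000 permutations can give, 4e-04 and 0.0040). The 25 adjacent genes from YEATS4 to ATP2B1 had a median B minus G of 0.13, with 21 positive, above the 95th percentile of the highest window in permuted orders (0.12). No window passed that level for H minus M (highest 0.23, against 0.25) or for knockdown minus control (0.22, against 0.25).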
